A study of Mus musculus with 6 samples.

How the data were processed

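The study measured messenger RNA in single basal cells of the dorsal interfollicular epidermis of CD1 mice, an outbred strain, by droplet sequencing with unique molecular identifiers (UMIs). Per the labels' protocols, epidermal cells were sorted for surface alpha6 integrin and against CD34, a gate meant to hold interfollicular and infundibular basal cells and to leave out bulge cells of the hair follicle, and 6000 cells were loaded per channel of a 10x Genomics Chromium chip (V2 chemistry). The labels name 6 samples, each the only sample of its condition. These are an untreated control, skin stretched for 1 day, skin stretched for 4 days, skin given the phorbol ester TPA, and skin stretched for 2 days in mice that received either trametinib or CCG203971. Trametinib, given by mouth at 2 mg per kg body weight daily, inhibits the kinases MEK1 and MEK2. CCG203971, injected daily at 100 mg per kg, inhibits, per the labels, MAL, a cofactor of the transcription factor SRF. TPA was applied daily for 2 days as 200 µl of a 0.02 mg/ml solution.

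The deposited values are raw UMI counts per gene and cell, with no normalization. Per the submitters' processing notes the tools were Cell Ranger 3.0.2 and Seurat 3.0.1 and the genome build was mm10, while per the file headers the counts of the 2 day 2 libraries came from software version 3.1.0. How cells were called from droplets is not given in the sources used here. The trametinib and CCG203971 libraries are separate matrices of 31053 genes. The other 4 conditions share a single deposited matrix of 27998 genes and 28665 barcodes, whose barcodes carry the numbers 1 to 6 and no sample name. No cell of that matrix was therefore given to a condition, and no comparison between its conditions was made. Its barcode numbers were described each on its own, by value, range and median. Of the gene identifiers, 27514 were shared by both gene sets, and contrasts over the 2 day 2 libraries and the 6 barcode numbers, 8 sets of cells from at most 6 samples, used those.

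Cells with at least 500 genes and under 10% mitochondrial UMIs were kept. This left 4458 of 6339 barcodes (70.3%) and 16.6 M UMIs for trametinib, 6248 of 6978 barcodes (89.5%) and 20.6 M UMIs for CCG203971, and 24701 cells of the shared matrix. The doublet caller Scrublet, in scanpy 1.11.5, marked between 0.0543% and 0.350% of cells in each of the 8 sets. That is under the 0.5% below which the caller is taken not to have worked, so no cell was removed as a doublet and doublets remain in all values.

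Counts were summed over the cells of a library and scaled to CPM by its total UMIs. The ratio of the 2 day 2 libraries was taken as log2 of CPM plus a pseudocount of 1, trametinib over CCG203971, which understates the ratio of low genes. Genes were compared if at least 1 library reached 25 CPM, which 4824 genes did after mitochondrial, ribosomal protein, unnamed model and sex-linked genes were left out. Fold ratios without a pseudocount carry the exact 95% interval of a ratio of 2 Poisson counts, CPM values an exact Poisson interval and shares of cells an exact Clopper-Pearson binomial interval. All of these cover counting error only. With 1 library per drug there was no test between drugs and no p-value, and a count of genes at least 2-fold apart describes the size of differences between 2 libraries. Where a library held 0 UMIs of a gene, a floor of 3 UMIs in that library gave a bound of the fold. The exact 95% interval reaches lower, and its low end is given beside such a fold.

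The tests, the 20 gene lists, the markers and the rule for named genes were fixed before the data were examined. The core G2-M genes, the rule for naming clusters, the tests of depth and of dissociation, the settings without cluster 11, without Tubb4b and without the cells of highest doublet scores, and single genes named as such were chosen after. The named genes are the 12 with the largest ratio in each direction and, of each gene list, up to 4 members with the largest and smallest ratio at 5 CPM or more, some of which are not reported here. For the contrast within these sets they are the 8 genes in each direction whose smallest ratio over the sets is largest, and for the shared matrix the 10 genes with the widest range. The 20 gene lists cover MEK-ERK feedback, AP-1 and immediate early genes, SRF-MAL and YAP-TEAD targets, S phase, G2 and M phase, wound keratinocyte genes, basal keratins with the basement membrane, cell-cell adhesion, early differentiation, Notch, EGFR ligands, inflammatory cytokines, interferon, heat shock, cholesterol synthesis, ribosome biogenesis, glycolysis, apoptosis and sex-linked genes. A list's median ratio was placed among those of 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. Intervals of list medians come from 1000 Poisson resamplings of the counts. Under Other observations, brackets after medians of the sets of 4 genes and of the heat shock list are of another kind. They are the median plus or minus the median absolute deviation over the genes, a spread between genes and not counting error.

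A cell was counted above the cycling limit if it held at least 3 UMIs of the S and G2-M lists, 82 genes together, after thinning to 2000 UMIs. Cells with fewer UMIs, 875 of trametinib and 1610 of CCG203971, were left out of that share. Within each set the cells above and below the limit were then compared, leaving out the cell cycle genes themselves. Cells were clustered with the Leiden method (leidenalg 0.10.2, resolution 1, 30 neighbours, 30 components of 2000 variable genes), the 2 day 2 libraries together and the shared matrix on its own. A cluster was named after 1 of 15 marker classes if at least 3 of that class's markers stood among its 30 leading genes with no tie, a rule set after the clusters were seen on markers fixed before. The alternatives covered the filter on cells, TMM and median of ratios scaling, thinning, the floor, the pseudocount, the cells included, the cycling limit and the clustering settings.

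The calculation of ratios and intervals was tested on simulated data drawn from the means and library sizes of the 2 day 2 libraries. Of 100 genes set to a fold of 3 and 100 set to a fold of 8, 100% were found at least 2-fold apart in the right direction, as were 0 of 4288 unchanged genes. Of 4488 intervals, 94.9% held the true ratio. The simulated counts were Poisson draws without variation between animals or libraries, so they check counting error only. Gene positions come from GENCODE M21 on GRCm38, the assembly that mm10 names, 1-based, and 99.6% of the gene identifiers of the day 2 libraries were found there. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.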

Results

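Messenger RNA was counted in single basal cells of the dorsal epidermis of CD1 mice under 6 conditions, with 1 sample per condition. In the stretched conditions a self-inflating hydrogel under the back skin expanded it. The 2 libraries with their own matrices came from skin stretched for 2 days in mice given trametinib or CCG203971. The trametinib library held 6339 barcodes and 18.5 M UMIs. Its 4458 passing cells had a median of 3458 UMIs and 3.45% mitochondrial UMIs. The CCG203971 library held 6978 barcodes and 21.1 M UMIs, and its 6248 passing cells had a median of 3170.5 UMIs and 1.64% mitochondrial UMIs. A gene at 0 UMIs could have been present at up to 0.181 CPM in the trametinib library and 0.146 CPM in the CCG203971 library. The other 4 conditions formed 1 matrix of 28665 barcodes and 242 M UMIs, with 6 barcode numbers that no label ties to a condition. A library of skin stretched for 2 days without a drug was not analysed here.

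The first comparison addressed how basal cells of stretched skin differed between inhibition of MEK and inhibition of MAL. Crip1, a small LIM domain protein, was at 593 CPM (95% counting interval 581 to 605) in the trametinib library and 3.35 CPM (2.61 to 4.24) in the CCG203971 library, a ratio of 177 (140 to 228). Postn, the matrix protein periostin, was at 97.53 against 0.777 CPM, a ratio of 125 (77.0 to 220). Pthlh, parathyroid hormone-related protein, was at 40.7 against 1.21 CPM (ratio 33.5, 22.5 to 52.2). S100a9, a calcium-binding protein of inflamed epidermis, was at 180.5 against 8.84 CPM (ratio 20.4, 17.6 to 23.8). Both Postn and Pthlh stood on the marker list of the hair follicle bulge and outer root sheath. Without the follicle-type clusters the log2 ratio of Pthlh was 2.80 instead of 4.24, and among cells below the cycling limit that of S100a9 was 2.63, of Postn 4.96 and of gene Pthlh 2.81. Pthlh was itself a leading gene of follicle-type cluster 5, of which 98.3% were trametinib cells. Leaving that cluster out lowers the Pthlh ratio by construction.

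The other 8 genes with the largest ratios toward trametinib were led by Stmn1, which destabilises microtubules, at 59.2 against 2.43 CPM (ratio 24.4, 18.4 to 33.1). Tppp3, a tubulin-binding protein, had a ratio of 23.7 (15.6 to 37.7). The secreted proteins Igfbp7 (80.4 against 3.98 CPM), Sparc (94.6 against 5.29 CPM) and Ptn (100.2 against 6.85 CPM) had ratios of 20.2, 17.9 and 14.6. Clca3a1 (62.0 against 3.11 CPM), the protease inhibitor Stfa3 (61.5 against 3.35 CPM) and Krt4, a keratin of mucosal epithelia (39.0 against 2.09 CPM), had ratios of 19.9, 18.4 and 18.7.

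In the CCG203971 library, Cyp2b10, a cytochrome P450 induced by drugs in liver, was at 325 CPM (317 to 333) against 5.43 CPM (4.37 to 6.68), a ratio of 59.8 (48.6 to 74.5). Egr1, an immediate early transcription factor, was at 154 against 7.55 CPM (ratio 20.4, 17.1 to 24.6). Cnn3, the actin-binding protein calponin 3 and a member of the SRF-MAL list, was at 137 against 5.19 CPM (ratio 26.4, 21.3 to 33.1). Skint11, of a family of immunoglobulin-like proteins of skin and thymus, had 1125 UMIs against 1, a ratio of 905 with a counting interval of 162 to 35775. Lefty1, a secreted inhibitor of Nodal signalling, had 829 UMIs against 1, a ratio of 667 (119 to 26370).

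Further genes toward CCG203971 were the serpin Serpina3k, at 77.6 against 1.21 CPM (ratio 64.3, 41.5 to 106), and the chemokine receptor gene Cxcr2, at 77.0 against 2.17 CPM (ratio 35.4, 25.5 to 50.8). Cxcr2 stood on the neutrophil marker list, of which Retnlg and G0s2 had 0 UMIs in both libraries and Csf3r had 1 UMI in each. Gsta4 and Gpx2, enzymes that use glutathione, were at 58.1 against 2.54 CPM and 45.2 against 2.23 CPM, ratios of 22.9 and 20.2. Smarcd3, a subunit of the SWI/SNF chromatin remodelling complex, had a ratio of 27.3, Maob, a monoamine oxidase, of 21.9 and Tango6 of 14.4. Skint11, Cyp2b10, Serpina3k, Stfa3 and Clca3a1 belong to families with near-identical copies, between which reads can be split, so their values are uncertain.

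On GRCm38/mm10, Crip1 (ENSMUSG00000006360) lies on chromosome 12 from 113146316 to 113153879, plus strand. Postn (ENSMUSG00000027750) lies on chromosome 3 from 54361109 to 54391037, plus strand, and Cnn3 (ENSMUSG00000053931) on chromosome 3 from 121426497 to 121458207, plus strand. Egr1 (ENSMUSG00000038418) lies on chromosome 18 from 34859823 to 34864984, plus strand. Cyp2b10 (ENSMUSG00000030483) lies on chromosome 7 from 25897620 to 25926624, plus strand, and Lefty1 (ENSMUSG00000038793) on chromosome 1 from 180935022 to 180938400, plus strand.

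Of 4824 genes at 25 CPM or more, 277 were at least 2-fold higher in the trametinib library and 526 at least 2-fold higher in the CCG203971 library, so that 34.5% of these lay toward trametinib. With TMM scaling the numbers were 446 and 316 (58.5%), and with median of ratios scaling 504 and 275 (64.7%). The median log2 ratio of all compared genes was -0.16 as scaled by total UMIs, 0.10 with TMM and 0.16 with median of ratios. These numbers describe sizes of differences between 2 libraries, not between conditions, and have no replicate check.

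**Figure D1:**
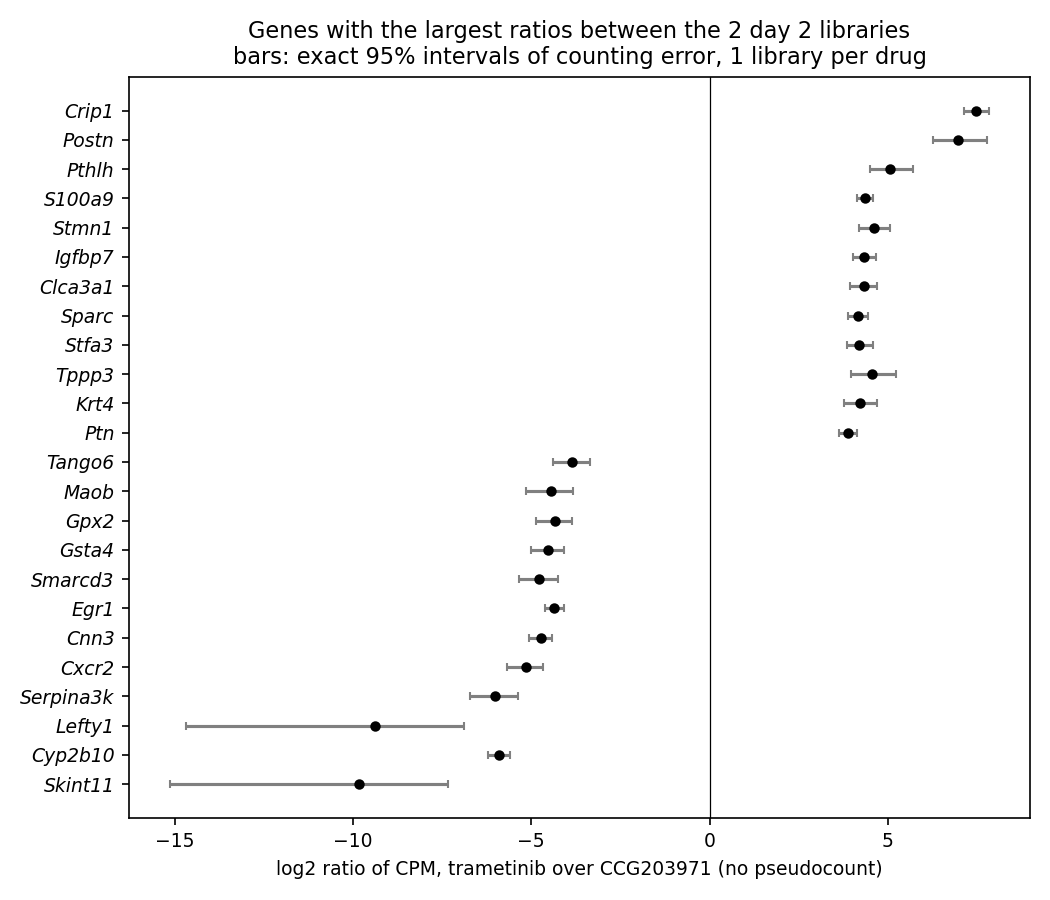
Log2 ratio of CPM without a pseudocount, trametinib over CCG203971 (x axis), for the 24 genes with the largest ratios among genes at 25 CPM or more in at least 1 library (y axis); points are the ratios and bars their exact 95% intervals of counting error, with 1 library per drug. Crip1 lay farthest toward trametinib, a ratio of 177, and Skint11 and Lefty1, each with 1 UMI in the trametinib library, farthest toward CCG203971 and with the widest intervals.

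Genes that report MEK-ERK signalling went both ways. Of 14 measured members, 6 were at least 2-fold higher in the trametinib library, 2 at least 2-fold higher in the CCG203971 library and 6 lay within 2-fold, with a median log2 ratio of 0.76 (counting interval 0.66 to 0.91). The 2 lower in the trametinib library were Dusp6, the phosphatase that removes phosphate from ERK, at 37.7 against 170 CPM (log2 -2.15), and the transcription factor Etv5, at 8.39 against 67.0 CPM (-2.86). Its relative Etv4 was at 18.5 against 2.14 CPM (2.64) and Phlda1 at 18.1 against 1.36 CPM (3.01). Without the follicle-type clusters the median was 0.57.

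Of 20 AP-1 and immediate early genes, 5 were at least 2-fold higher in each library and 10 lay within 2-fold. Fos was at 35.7 against 180 CPM (log2 -2.30) and Egr1 at -4.18, while Fosl1 (2.04) and Egr2 (1.97) lay toward trametinib. Without the follicle-type clusters Egr2 was at 0.48, and without day 2 cluster 11, a small trametinib cluster led by Cxcl2 and Ccl20, Fosl1 was at 1.21. Egr2 was among the 10 leading genes of follicle-type cluster 5 and Fosl1 among those of cluster 11, both nearly all trametinib cells. Leaving these clusters out lowers both ratios by construction. The list's median was -0.15, and it turned to 0.08 with TMM and 0.13 with median of ratios scaling. Without cluster 11 it was -0.29, and without the follicle-type clusters -0.40.

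SRF-MAL cytoskeletal genes lay mostly within 2-fold, 17 of 20, with 2 higher in the trametinib library and 1 in the CCG203971 library. Tpm1 (log2 1.03) lay toward trametinib, and Cnn3 (-4.48) and Wdr1 (-0.81) toward CCG203971. The median of 0.20 (0.14 to 0.31) was 0.13 without the follicle-type clusters, 0.42 with TMM and 0.47 with median of ratios scaling. SRF-MAL members under 5 CPM in both libraries were not among the 20 and were looked at after the values were seen. Pdlim7 had 32 against 7 UMIs, and Acta2 and Cnn1 12 against 0 each, toward trametinib. Itga5 had 47 against 98 UMIs, toward CCG203971. Tagln had 4 against 6 UMIs, Tgfb1i1 4 against 2 and Myl9 1 in each. Of 12 YAP-TEAD targets, 10 lay within 2-fold, with Tgfb2 at 1.18, Crim1 at 0.70, Cyr61 at -0.67 and Nuak2 at -1.39. Their median was 0.07 (-0.04 to 0.16), 0.01 without cluster 11, 0.03 without the follicle-type clusters and 0.29 with TMM. Members under 5 CPM in both libraries were not among the 12 and were looked at after the values were seen. Of these, Ctgf had 54 against 5 UMIs and Nt5e 35 against 8, both toward trametinib. Arhgef17 had 3 against 2 UMIs and Ankrd1 0 in each.

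Of 13 measured genes of early differentiation, 7 were at least 2-fold higher in the trametinib library, 1 was at least 2-fold higher in the CCG203971 library and 5 lay within 2-fold, with a median log2 ratio of 1.12 (0.96 to 1.34). Krt10, a keratin of suprabasal cells, was at 1422 against 139 CPM (3.35) and Mt4 at 10.4 against 0.389 CPM (3.04). Ptgs1 (-0.54) and Lor, the cornified envelope protein loricrin (-1.32), lay toward CCG203971. Ivl, the envelope protein involucrin, was under 5 CPM in both libraries, so it was not among the 13, and was looked at after the values were seen. It had 1 UMI against 49, a ratio of 39.4 toward CCG203971 (6.75 to 1588). Of 9 Notch pathway genes, 7 lay within 2-fold, with Notch3 at 1.12, Jag2 at 0.76, Rbpj at -0.24 (0.04 with median of ratios scaling) and Notch1 at -1.005. The median of the Notch list was 0.63.

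Wound and stress genes of keratinocytes had a median log2 ratio of 2.04 (1.64 to 2.40), with 8 of 13 at least 2-fold higher in the trametinib library, 0 at least 2-fold higher in the CCG203971 library and 5 within 2-fold. S100a9 was at 4.21 and Stfa3 at 3.85. Slpi was at -0.35, and Krt16, a keratin of wounded skin, was at -0.14 by total UMIs but at 0.09 with TMM and 0.15 with median of ratios scaling. Among cells below the cycling limit gene Slpi was at 0.56 and gene Krt16 at 0.58. The list's median was 1.21 without cluster 11, which held 115 trametinib cells, and 1.34 without the follicle-type clusters. Stfa3 and Fosl1 of this list were among the leading genes of cluster 11, so the drop without it is partly by construction. Sprr2d had 0 UMIs in the CCG203971 library. Against the floor it was 56.8-fold higher in the trametinib library, and the exact interval reached down to 45.6-fold. The median with this member at its bound against the floor was the same 2.04.

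Inflammatory cytokines and NF-kB targets had a median of 1.13 (1.02 to 1.24), with 6 of 11 at least 2-fold higher in the trametinib library, 1 in the CCG203971 library and 4 within 2-fold. Without cluster 11 the median was 0.58. That cluster was led by Cxcl2, Ccl20, Cxcl1 and Tslp of this list and by Epgn, so leaving it out lowers their values by construction. Cxcl2, a chemokine that attracts neutrophils, had 326 UMIs against 0. Against the floor it was 135-fold higher in the trametinib library, and the exact interval reached down to 109-fold. The median with Cxcl2 at its bound was again 1.13. Ccl20 was at 117 against 12.5 CPM (log2 3.12, and 1.74 without cluster 11). Ccl2 (-0.34) and Tnfaip3 (-1.16) lay toward CCG203971. Of 8 ligands of the EGF receptor family 4 were measured, and all 4 were at least 2-fold higher in the trametinib library, with Nrg1 at 2.34, Epgn at 2.13 (1.31 without cluster 11), Tgfa at 1.21 and Hbegf at 1.04, a median of 1.67 (1.48 to 1.85). Under 5 CPM in both libraries, and looked at after the values were seen, Egf had 19 against 71 UMIs, a ratio of 3.01 toward CCG203971 (1.79 to 5.28), and Areg 19 against 0 UMIs.

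Cholesterol synthesis genes also lay toward trametinib, with 8 of 17 at least 2-fold higher, 9 within 2-fold and a median of 0.96 (0.87 to 1.08). Sc5d was at 0.15 and Nsdhl at -0.14, the sign of which turned under both other scalings. Of 15 glycolysis genes 12 lay within 2-fold, with a median of 0.41. The glucose transporter gene Slc2a1 (1.18) and Pfkp (1.14) lay toward trametinib, and Eno1 (-0.39) and Pfkl (-1.11) toward CCG203971.

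Genes of the basement membrane and basal keratins had a median of 0.48 (0.44 to 0.50), with 15 of 16 within 2-fold. The basal keratin Krt5 was at 2917 against 1577 CPM (0.89) and Lamb3 at 0.85, but Itgb4, the integrin of hemidesmosomes, was at -0.93 and the laminin gene Lama5 at -1.75. Of 21 cell-cell adhesion genes 18 lay within 2-fold and 3 were at least 2-fold higher in the trametinib library, with a median of 0.39. Pkp1 was at 1.16 and Cldn1 at 1.12. Dsc3 (-0.26) and Ctnnb1 (-0.24) turned to 0.03 and 0.04 with median of ratios scaling.

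The heat shock list had a median of -0.15, which turned to 0.07 with TMM and 0.13 with median of ratios scaling. Of its 12 genes 10 lay within 2-fold. Hspb1, a small heat shock protein, was at 302 against 2060 CPM (log2 -2.77), Hspa8 at -1.01, Bag3 at 0.45 and Dnajb1 at 0.78. Interferon genes had a median of -0.10, which turned to 0.12 and 0.17 under the same scalings, with 7 of 10 within 2-fold. Ifi27l2a was at 3.603 and Stat2 at 0.41, against Ifi35 at -1.03 and Bst2 at -2.07. The interferon median was -0.61 among cells below the cycling limit.

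Ribosome biogenesis genes had a median of -0.19, turning to 0.04 and 0.09 under the same scalings, with 15 of 16 within 2-fold. Npm1 was at 0.33, Nop58 at 0.17, Rrp9 at -0.63 and Bop1 at -1.30. Of 10 apoptosis regulators 9 lay within 2-fold, with Pmaip1 at 1.18, Mcl1 at 0.73 and Bcl2 at -0.44. Their median of -0.02 (-0.12 to 0.13) did not stand apart from 0 by counting error, and it was 0.19 with TMM. The Y-linked genes Kdm5d (-0.52), Eif2s3y (-0.38), Ddx3y (-0.20) and Uty (-0.12) had a median of -0.29, -0.07 with TMM, and Ddx3y and Uty turned sign under TMM and median of ratios scaling. Xist had 1 UMI in each library.

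Among matched random lists, 13 of the 20 list medians lay above percentile 95 and 0 below 5, so a high percentile set a list apart from few others. The S phase list was at percentile 99.8, SRF-MAL at 98.4, glycolysis at 99.3, Notch at 99.8, basal genes at 99.9, adhesion at 99.9 and EGFR ligands at 99.96. The MEK-ERK, G2-M, wound, differentiation, inflammatory and cholesterol lists were at percentile 100. YAP-TEAD was at 91.1, apoptosis at 84.7, interferon at 66.2, AP-1 at 47.8, sex-linked at 41.6, heat shock at 31.5 and ribosome biogenesis at 12.6. TMM scaling moved the median of SRF-MAL from 0.20 to 0.42, of S phase from 0.20 to 0.41, of adhesion from 0.39 to 0.60 and of glycolysis from 0.41 to 0.64.

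**Figure D2:**
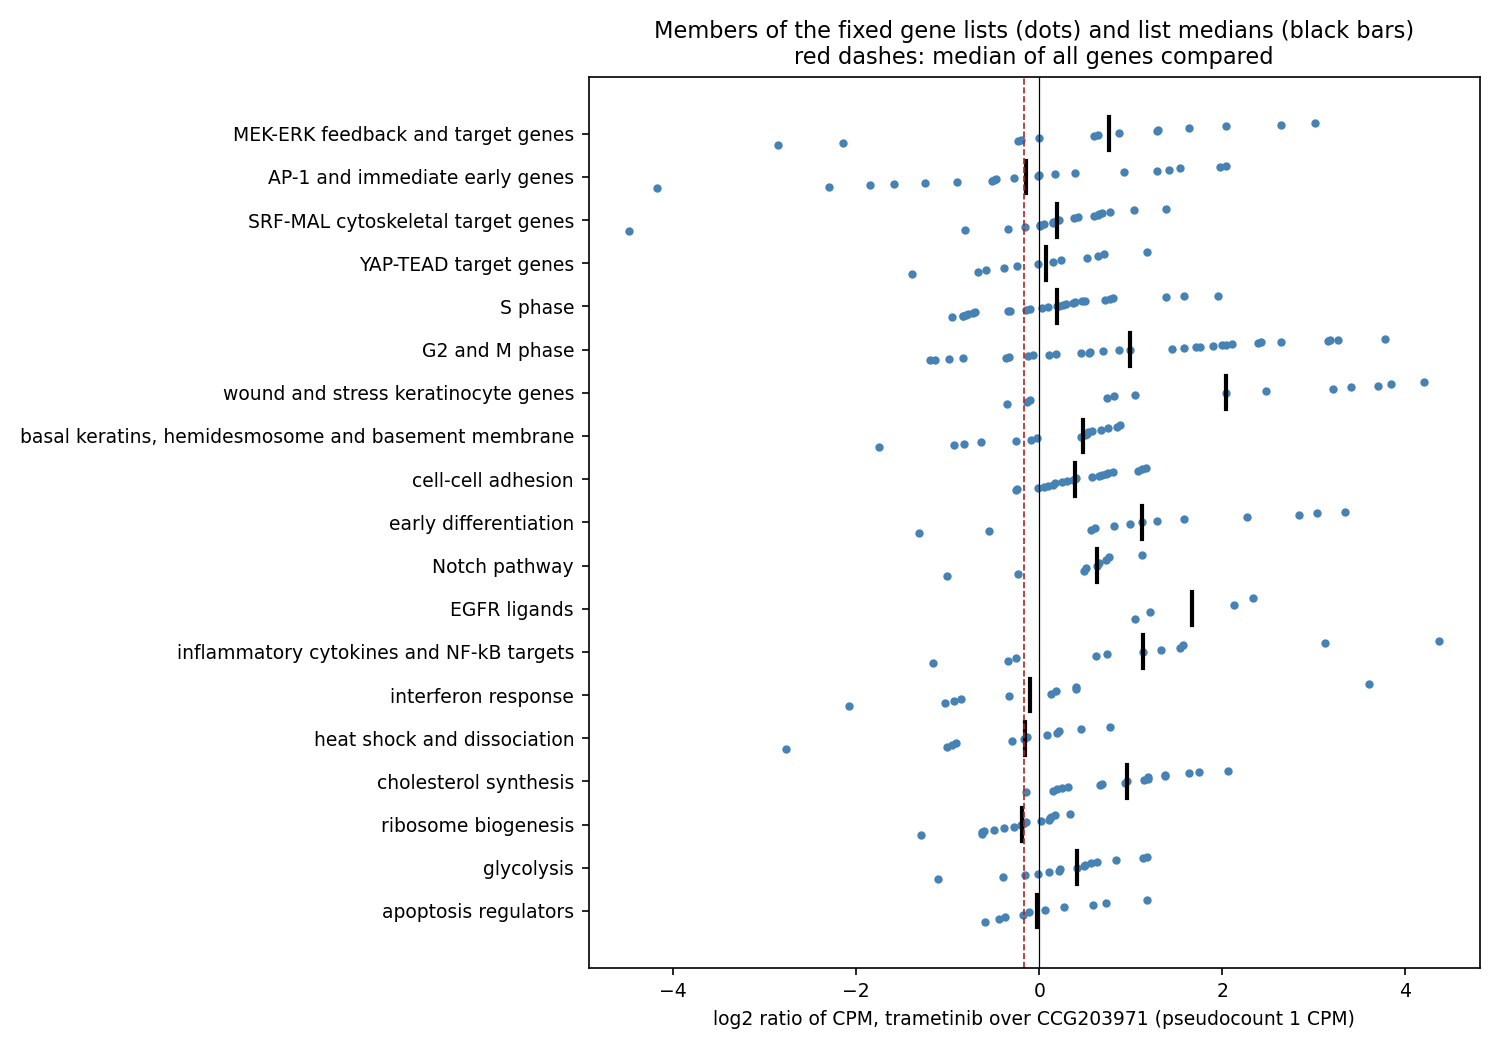
Log2 ratio of CPM plus 1, trametinib over CCG203971 (x axis), for the members of the gene lists other than the sex-linked list (y axis), with dots for measured members, black bars for list medians and a red dashed line for the median of all compared genes, -0.16. Wound genes had the highest median at 2.04 (1.21 without cluster 11), and the small negative medians of AP-1, interferon, heat shock, ribosome biogenesis and apoptosis genes turned positive with TMM or median of ratios scaling.

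Markers of other cell types were mostly near 0 in the sorted cells. Col1a1 had 1 UMI in the trametinib library and 0 in the CCG203971 library, Ptprc 1 and 0, Tyrobp 5 and 9, and Cd34, the marker sorted against, 0 and 8. Among the melanocyte, Merkel, endothelial, smooth muscle and erythroid markers, Pmel had 7 and 2 UMIs, Krt18 34 and 2, Pecam1 27 and 38, Acta2 12 and 0, and Hba-a1 13 and 0. Markers that keratinocytes can also express differed more, with Cd74 at 37.0 against 7.53 CPM, H2-Ab1 at 25.8 against 3.59 CPM, Il1r2 at 133 against 31.0 CPM, Thy1 at 37.1 against 93.7 CPM and the sebaceous marker Scd1 at 22.4 against 9.13 CPM. The follicle markers Krt79 (85.8 against 10.5 CPM), Fst (102 against 12.0 CPM), Barx2 (128 against 23.9 CPM) and Sox9 (26.6 against 3.06 CPM) were each higher in the trametinib library. Others of these lists were not, with Dkk3 at 15.5 against 15.3 CPM, Cst6 at 127 against 112 CPM, Lgr5 at 8 against 11 UMIs and Atp6v1c2 at 8 against 20 UMIs.

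The next comparison addressed genes of the cell cycle. Genes of G2 and M phase had a median log2 ratio of 0.99 (0.75 to 1.34), with 15 of 31 at least 2-fold higher in the trametinib library, 2 in the CCG203971 library and 14 within 2-fold. Cdk1, the kinase that drives mitosis, was at 19.3 against 0.486 CPM (3.77) and Ube2c had 158 against 2 UMIs (3.26), while Gtse1 was at -1.14 and Dlgap5 at -1.20. S phase genes had a median of 0.20 (0.05 to 0.28), with 24 of 27 within 2-fold, Uhrf1 at 1.95, Gmnn at 1.58, Pola1 at -0.83 and Gins2 at -0.95. Among cells below the cycling limit, a choice made on these genes, the G2-M median was 0.29 and the S phase median -0.33. The sums over the lists were close, at 1496 against 1540 CPM for G2-M and 862 against 885 CPM for S phase. Tubb4b alone, at 427 against 761 CPM, was a large part of the G2-M sums and ran toward CCG203971. The close G2-M sums therefore do not show equal levels of the other G2-M genes.

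The share of cells with at least 3 UMIs of the S and G2-M lists was 68.8% (67.3 to 70.3) of 3583 trametinib cells and 83.4% (82.3 to 84.5) of 4638 CCG203971 cells after thinning, a difference of -14.6 percentage points. Without thinning it was 81.7% and 85.9%. Cells at exactly the limit made up 19.8% and 15.4%, and cells just below it 16.4% and 10.5%. Tubb4b, a tubulin also expressed outside the cell cycle, alone gave 18.1% of the list's UMIs in the trametinib library and 31.4% in the CCG203971 library, at 427 against 761 CPM. Hmgb2, a chromatin protein that is also broadly expressed, gave a further 10.9% and 9.28%, so the share is not a count of cycling cells. Without Tubb4b, a setting chosen after its level was seen, the shares were 53.6% and 60.9%.

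A core of 15 G2-M genes, likewise chosen after the lists' values were seen, ran the other way. It held Mki67, Top2a, Ube2c, Birc5, Cdk1, Ccnb1, Ccnb2, Cdc20, Cenpa, Aurkb, Nusap1, Tpx2, Hmmr, Cdca3 and Cdca8. Of its 12 measured genes 10 were at least 2-fold higher in the trametinib library, 0 in the CCG203971 library and 2 lay within 2-fold. Dlgap5, Gtse1 and Hjurp (log2 -0.98), G2-M genes toward CCG203971, were not in it, so the choice of genes could set this direction. At least 3 core UMIs were held by 102 of 3583 trametinib cells (2.85%, 2.33 to 3.45) and by 2 of 4638 CCG203971 cells (0.0431%, 0.00522 to 0.156). Without thinning the shares were 3.096% and 0.208%. After thinning, at least 1 core UMI was found in 10.2% and 7.20% of cells. Of thinned trametinib cells in cluster 8, led by genes of differentiation, 6.87% held 1 as well, with a median of 4345 UMIs before thinning. Thinned CCG203971 cells of clusters 8 and 9 were at 7.76%, with a median of 4797 UMIs before thinning. Nearly all of these were in cluster 9, which no marker of differentiation led, so a background for the 7.20% of the CCG203971 library was not established. Cells outside the cycling-like cluster with at least 3 core UMIs were 15 of 3485 (0.430%) and 2 of 4638 (0.0431%). Summed core genes stood at 187 against 40.3 CPM.

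**Figure D3:**
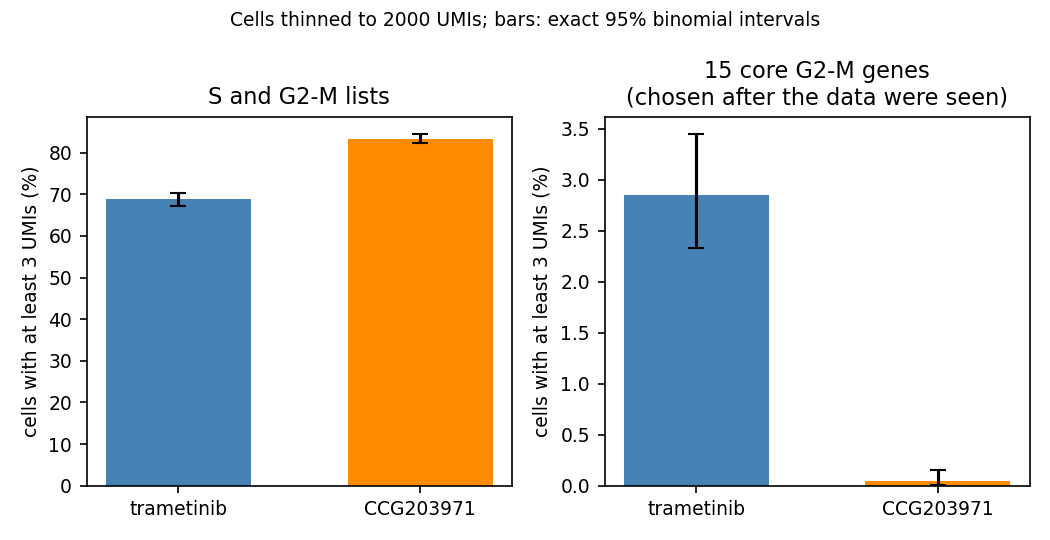
Percent of cells (y axis) with at least 3 UMIs of the S and G2-M lists (left) or of the 15 core G2-M genes, chosen after the data were seen (right), in the trametinib and CCG203971 libraries (x axis) after thinning to 2000 UMIs, with columns for the share and lines for its exact 95% binomial interval. The lists gave 68.8% and 83.4%, and the core genes 2.85% and 0.0431%.

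Infundibulum-like cells, of the upper hair follicle, made up 18.0% (16.9 to 19.2) of trametinib cells, nearly all in cluster 5, and 5.57% (5.01 to 6.17) of CCG203971 cells, mostly in cluster 10. Cluster 5 had 8 infundibulum markers among its 30 leading genes and 2 among the first 10, and cluster 10 had 4 and 1. The 2 shares may therefore not be of 1 class. Cluster 5 was also led by Pthlh and Sox9 of the bulge and outer root sheath list. Cluster 8, led by Krt10, Endou and Krt1, was differentiating-like and held 673 trametinib cells (15.1%, 14.1 to 16.2). Cluster 9 held 426 CCG203971 cells (6.82%, 6.21 to 7.47). It had 3 differentiation markers among its 30 leading genes but 0 among the first 10, which were led by Spink4 and held Krt16 and Krt6a of stressed skin, so these clusters were not compared as a class. The cycling-like cluster 12 held 99 trametinib cells (2.22%, 1.81 to 2.70) and 1 CCG203971 cell (0.0160%, 0.000405 to 0.0891). In each of the 13 clusters at least 98.3% of cells came from a single library, so a cluster may be a library and not a type. The sort on alpha6 integrin, the depth and the filter, which left out 29.7% and 10.5% of barcodes, can set these shares.

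Cells above the cycling limit were compared with cells below it within each of 8 sets of cells, the 2 day 2 libraries and the 6 barcode numbers of the shared matrix. The barcode numbers belong to 4 samples, so the 8 sets stand for at most 6 samples and are not independent replicates. Calm3, a calmodulin gene, was higher in cells above the limit in 8 of 8 sets, with a median log2 ratio of 0.41 (0.25 to 0.75 over the sets). Rfc2, a subunit of the clamp loader of DNA replication, was at 0.87 (0.15 to 1.19). The splicing factors Srsf7 (0.36, 0.16 to 0.99) and Srsf1 (0.27, 0.17 to 0.57) were higher in 8 of 8, as were Hpf1, a partner of the DNA repair enzyme PARP1 (0.43), Mesd (0.35), Znhit6 (0.19) and Txnl1 (0.16). Btg1, an inhibitor of proliferation, was lower in cells above the limit in 8 of 8 (-0.21, -0.95 to -0.09), as were Ypel3 (-0.18), Use1 (-0.24), Kxd1 (-0.17), Hibadh (-0.16), and Ndufa6 (-0.18), Uqcc3 (-0.15) and Cox7a2l (-0.16) of mitochondrial respiration. These genes were picked for being alike in direction over the sets. At a limit of 5 UMIs the range over the sets crossed 0 for Znhit6, Ypel3, Kxd1, Hibadh, Uqcc3 and Cox7a2l. With the core G2-M genes as the divide, a choice made after seeing the data that 7 sets had cells enough for, it crossed 0 for Mesd (lowest -0.13), Znhit6 (lowest -0.15), Btg1 (highest 0.0042), Ypel3 (highest 0.29), Kxd1 (highest 0.79) and Hibadh (highest 0.084). The median of Calm3 was then 1.31 and that of Btg1 -1.04.

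Of the lists, MEK-ERK genes (median 0.17), ribosome biogenesis (0.14) and heat shock (0.06) lay above 0 in 8 of 8 sets. SRF-MAL (0.21), basal genes (0.05), cholesterol synthesis (0.18) and glycolysis (0.11) did so in 7 of 8. Early differentiation was below 0 in 6 of 8 (-0.15), as was adhesion (-0.05), and the sex-linked list in 7 of 8 (-0.05). With the core divide early differentiation was below 0 in 7 of 7 (-1.06, -2.18 to -0.34), and so were sex-linked genes (-0.35, -0.44 to -0.06). Adhesion was below 0 in 6 of 7 (-0.20). SRF-MAL (0.42, 0.23 to 0.51) and glycolysis (0.28, 0.01 to 0.70) were above 0 in 7 of 7. MEK-ERK genes were so in 5 of 7, and ribosome biogenesis and heat shock in 6 of 7. As the sex-linked list also went 1 way, a uniform direction did not by itself set a list apart.

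The matrix of the control, stretch day 1, stretch day 4 and TPA samples was described by barcode number, with no condition and no comparison. Of the 10 genes with the widest ranges over its 6 barcode numbers, 7 stood on the wound and stress list, and BC100530, Sprr2a3 and Lcn2 did not. S100a8 ran from 3.58 to 8538 CPM (median 62.8) and S100a9 from 2.35 to 6057 CPM (median 20.01). The wound keratins ran from 3.77 to 2965 CPM for Krt6a (median 353), 0.188 to 736 CPM for Krt6b (69.6) and 6.80 to 1580 CPM for Krt16 (230.0). BC100530, a stefin, ran from 19.7 to 9841 CPM (702), Sprr2a3 from 1.79 to 1413 CPM (40.1), Sprr2d from 0 to 271 CPM (7.26), Sprr1b from 0.188 to 170 CPM (19.9) and Lcn2 from 1.79 to 421 CPM (41.7). Sprr2 and stefin genes have near-identical copies, so their values are uncertain.

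Summed over lists, wound genes ran from 647 to 23682 CPM over the barcode numbers (median 2608), EGFR ligands from 19.9 to 205 CPM (41.4), G2-M genes from 1345 to 4537 CPM (2471), S phase genes from 568 to 1370 CPM (1020) and cholesterol synthesis genes from 309 to 1356 CPM (596). Glycolysis ran from 1988 to 7547 CPM (3813), YAP-TEAD targets from 193 to 646 CPM (450), AP-1 from 1083 to 3135 CPM (1578), SRF-MAL from 3217 to 6299 CPM (4320) and early differentiation from 6852 to 15870 CPM (9215). MEK-ERK genes had a narrow range of 277 to 372 CPM (326), as did apoptosis regulators, 194 to 228 CPM (206), and basal genes, 28361 to 42059 CPM (33351). Inflammatory genes ran from 503 to 1054 CPM (609), Notch genes from 230 to 488 CPM (397), adhesion genes from 3410 to 7336 CPM (5941), interferon genes from 1819 to 3298 CPM (2703), heat shock genes from 3970 to 6024 CPM (4915), ribosome biogenesis from 2933 to 5512 CPM (3362) and sex-linked genes from 76.2 to 208 CPM (147). Across 5557 genes, which are not independent replicates, Pearson's r between barcode numbers ran from 0.789 to 0.954.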

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

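In this part Malat1, Krt10 and Egr1 were chosen after values were seen, and no explanation was tested. The filter left out 29.7% of the barcodes of the trametinib library and 10.5% of those of the CCG203971 library, and these cells enter only the settings without a filter. They held keratinocyte RNA, with Krt14 at 7221 CPM in the trametinib library (10560 CPM in passing cells) and 6264 CPM in the CCG203971 library (7671 CPM in passing cells). Malat1, a nuclear RNA, was at 112582 CPM in left-out and 31912 CPM in passing trametinib cells, and at 89733 and 30291 CPM in those of the CCG203971 library. Left-out cells of the CCG203971 library had Krt10 at 617 CPM (139 CPM in passing cells) and Egr1 at 331 CPM (154 CPM in passing cells). Those of the trametinib library had Krt10 at 1077 CPM (1422 CPM) and Egr1 at 13.1 CPM (7.55 CPM).

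In the matrix without sample names, the highest values of 10 genes stood above what a count of 0 allows, and they belong to no comparison. Their lowest values did not in each case, since Sprr2d was at 0 CPM in barcode numbers 1 and 6. Krt6b and Sprr1b were at 0.188 CPM in number 6, where the floor of 3 UMIs is 0.283 CPM. The log2 of CPM plus 1 of S100a8 spanned 10.86 over its 6 barcode numbers, S100a9 10.82, Krt6a 9.28, Krt6b 9.28, Sprr2a3 8.99, BC100530 8.89, Sprr2d 8.09, Krt16 7.66, Lcn2 7.24 and Sprr1b 7.17.

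For 10 lists the cells above the cycling limit differed from those below it in opposite directions in the 2 day 2 libraries. The difference between the libraries was not tested, and most values were close to 0. The median log2 ratios in the trametinib and CCG203971 libraries were -0.23 and 0.11 for wound genes, 0.063 and -0.11 for interferon genes, -0.011 and 0.060 for SRF-MAL genes and 0.033 and -0.055 for YAP-TEAD targets. They were -0.060 and 0.034 for glycolysis, -0.050 and 0.032 for adhesion, 0.022 and -0.020 for early differentiation and 0.065 and -0.028 for sex-linked genes. Basal genes were at -0.021 and 0.0083 and Notch genes at 0.034 and -0.0097.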

How the results depend on the processing

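The settings without the cells of highest doublet scores, without cluster 11, without Tubb4b and with the core G2-M genes were chosen after seeing the data; the others were planned. Of the values that answer a comparison, 55 kept their direction and size, 20 moved and 4 reversed. Of the other values 986 stayed within their intervals, 575 moved and 21 reversed. Fold intervals of genes carry no pseudocount, so for low genes the main log2 ratio can itself lie outside them. Fosl1, at log2 2.04 with a fold interval of 4.95 to 16.5, was such a gene. The number moved may therefore hold low genes that barely changed. The cause was not tested except where the setting's construction gives it. By scaling, genes at least 2-fold higher in the trametinib and CCG203971 libraries were 446 and 316 with TMM, and 504 and 275 with median of ratios, against 277 and 526. The MEK-ERK median was then 0.98 and 1.03, and the SRF-MAL median 0.42 and 0.47. Under TMM and median of ratios the sign turned for AP-1 (0.075, 0.13), interferon (0.12, 0.17), heat shock (0.074, 0.13), ribosome biogenesis (0.036, 0.094), gene Krt16 (0.090, 0.15) and gene Ddx3y (0.022, 0.080), and under median of ratios alone for gene Dsc3 (0.027), gene Ctnnb1 (0.040) and gene Rbpj (0.042). By construction, a floor of 5 CPM gave 552 and 1300 genes, and a floor of 100 CPM 113 and 126. A pseudocount of 10 CPM gave 311 genes toward CCG203971 and a MEK-ERK median of 0.49. Without the follicle-type clusters MEK-ERK was at 0.57, SRF-MAL at 0.13 and Krt16 at 0.046, and thinned to 2000 UMIs Krt16 was at 0.053. Among cells below the cycling limit MEK-ERK was at 0.98, S phase at -0.33, gene Uhrf1 at -0.0668, gene Slpi at 0.56 and Krt16 at 0.58. The difference in cycling share, -14.6 percentage points, was -4.28 without thinning, -8.75 at a limit of 2 UMIs and -7.25 without Tubb4b. With the core G2-M genes it was 2.80, and 2.81 with no filter, 2.89 with no thinning and 2.96 at 1 UMI or more. Removing called doublets was not run, but without the 5% of cells with the highest doublet scores 275 and 524 genes were at least 2-fold apart and the difference in cycling share was -14.1. No paired analysis was possible because each condition had 1 sample. Depth limits genes under about 25 CPM, where the floors of 0.181 and 0.146 CPM bound the ratios.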

Other observations

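In this part the core G2-M genes, the tests of depth and of dissociation, and the genes given by barcode number were chosen after values were seen, and the spread asked of a test before it could exclude an explanation was added after as well. In the matrix without sample names, Fkbp5, Zbtb16, Tsc22d3 and Serpina3n were among the 10 leading genes of a cluster of 3029 cells, 99.7% of them of barcode number 3, so their levels by number restate that cluster. Glucocorticoids are known to induce these genes, and Klf9 and Per1, but no list was fixed before and none was tested. Fkbp5 was at 89.9 CPM in number 3 and at 5.33 to 7.04 CPM in the other 5. Zbtb16 was at 117 CPM, against 30.9, 7.57, 3.03, 2.70 and 23.5 CPM in barcode numbers 1, 2, 4, 5 and 6. Tsc22d3 was at 373 CPM, against 48.3, 44.2, 17.1, 18.4 and 78.7 CPM. Klf9 was at 119 CPM in number 3, below the 128.0 CPM of number 6, and at 65.0, 31.5, 14.6 and 34.2 CPM in numbers 1, 2, 4 and 5. Serpina3n was at 91.2 CPM in number 3, against 5.93, 10.04, 3.18, 6.03 and 14.03 CPM in numbers 1, 2, 4, 5 and 6, and Per1 at 38.4 CPM, against 19.6, 11.2, 5.16, 10.6 and 18.2 CPM. The trametinib and CCG203971 libraries had Fkbp5 at 29.1 and 54.0 CPM, Zbtb16 at 68.1 and 55.0 CPM, Tsc22d3 at 304 and 284 CPM, Klf9 at 271 and 163 CPM, Serpina3n at 274 and 466 CPM and Per1 at 82.5 and 40.5 CPM. These CPM are not directly comparable with those of the shared matrix, which has another gene set. Ribosomal protein genes gave a median of 20.3% and 19.8% of UMIs per passing cell here, against 25.1% to 33.1% over the barcode numbers.

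Krt6a was at 53.8, 510, 196, 2965, 2262 and 3.77 CPM in barcode numbers 1 to 6, and Krt16 at 6.80, 333, 127, 1580, 1270 and 12.2 CPM. S100a8 was at 13.6, 54.1, 1130, 71.6, 8538 and 3.58 CPM, so the numbers highest in Krt6a were not all highest in S100a8. Krt15, a keratin of resting basal and bulge cells, was at 7019, 6337, 6742, 529, 1349 and 11502 CPM. Cells with at least 3 core G2-M UMIs made up 2.9996%, 10.6%, 2.53%, 37.9%, 27.1% and 4.50%, and cells above the limit of the full lists 61.3%, 72.1%, 53.5%, 77.5%, 77.9% and 61.0%.

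Without thinning, the share of cells with at least 3 core G2-M UMIs in the trametinib library was 14.9 times (8.42 to 28.6) that in the CCG203971 library. At equal depth, a measure seen before this test was set, it was 66.0 times (17.8 to 552), resting on 2 CCG203971 cells. This argues against depth per cell as the whole cause. Without the filter the ratio was 27.1 (11.3 to 85.2). Thinning again left out barcodes under 2000 UMIs, so 3667 trametinib and 4644 CCG203971 cells entered, against 3583 and 4638 with the filter. Most barcodes that the filter left out were thus not counted, so the filter as a cause was not decided. With at least 1 core UMI the ratio was 1.41 (1.21 to 1.64), and the planned S and G2-M lists ran the other way, at 0.825. Fewer cells in G2 or M phase under CCG203971 may account for the core genes alone, whose choice after values were seen could set this direction. Dlgap5 (log2 -1.20) and Gtse1 (-1.14), G2-M genes outside the core, lay toward CCG203971. Drug, animal and library cannot be separated with 1 library each, so fewer cells in G2 or M phase stays a hypothesis.

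Krt1, Krt10, Krtdap and Calm4 were higher in the trametinib library, with a median log2 ratio of 2.55, but they are from the high end of the early differentiation list, whose median was 1.12 and of which Lor (-1.32), Ptgs1 (-0.54) and Ivl (1 against 49 UMIs) lay the other way. Low-quality cells in that library as the cause were argued against by a median of 2.56 (2.03 to 3.08) among cells with at least 1000 genes and under 5% mitochondrial UMIs. That filter acts on single cells, so a difference in quality of the whole library stays open. Brackets after medians of these genes, and of the genes in the next paragraph, give the median absolute deviation over genes on either side. They are not intervals of counting error. Outside clusters 8 and 9, those with most markers of differentiation, the median was 1.13 (0.91 to 1.36). Cluster 8, of which 98.7% were trametinib cells, was itself led by Krt10, Krt1 and Calm4. None of the 4 genes stood among the first 10 of cluster 9, so leaving both out lowers the ratio by construction. A larger share of differentiating cells, as part or whole of the explanation, was neither shown nor excluded. A difference between the drugs or the animals stays open and untested.

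Dusp6, Etv5, Egr1 and Fos, genes known to follow ERK activity and the lowest members of their 2 lists, were lower in the trametinib library. Among cells of the stricter filter their median was -2.56, with a spread between genes of -2.93 to -2.19. The single genes ran from -4.13 (Egr1) to -2.13 (Dusp6) there, which argues against low-quality cells as the cause. A difference in quality of the whole library stays open, since the filter acts on single cells. Different cell classes stay open although the median was -2.55 (-2.86 to -2.24) outside every named cluster, because the unnamed cluster 1, 19.5% of CCG203971 cells, was itself led by Fos, Egr1 and Dusp6 and each cluster was nearly 1 library, so that the bound set for this test could not decide. A dissociation response in the CCG203971 library stays open, since the heat shock median was -0.15 (-0.64 to 0.33) with members on both sides, and 3 of 18 other immediate early genes were at least 2-fold lower in the trametinib library. Weaker ERK output under the MEK inhibitor may be the cause for these 4. Of the 14 measured MEK-ERK genes, though, 6 were at least 2-fold higher in the trametinib library, among them Etv4 and Phlda1. Only 2 were at least 2-fold lower there, and the list's median was 0.76.

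A pair of further hypotheses was tested on genes whose values had not been seen. Gsta4 and Gpx2 were higher in the CCG203971 library, which might reflect a wider NRF2 response. Of 21 other NRF2 targets, 4 were at least 2-fold higher in the CCG203971 library, 1 in the trametinib library and 16 lay within 2-fold. Hmox1 was at -2.84 and Gstm1 at 1.97. The median of these 21 lay at percentile 4.74 of matched random lists, but between 1.38 and 14.9 over the settings, which leaves it open. Of 21 measured HIF targets, 3 were at least 2-fold higher in the trametinib library, among them Ero1l (2.34) and Higd1a (1.10), 0 were in the CCG203971 library and 18 lay within 2-fold. The median of the 21 HIF targets, 0.43, lay at percentile 99.97 (99.87 to 100). As 13 of the 20 planned lists also lay above percentile 95, this could be a general feature of these libraries and was left open.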
